A study of Mus musculus with 4 samples.

How the data were processed

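Gene expression was measured on 4 Illumina mouse BeadChip arrays, each hybridised with biotin-labelled total RNA from a sample labelled Balb/c mouse thyroid. The labels give absorbed doses of 0, 0.85, 8.5 and 17 Gy and a time of 24 h, with 1 array at each dose. Per the labels' protocols, RNA was prepared from fresh-frozen tissue with a kit for lipid-rich tissue and its quality was checked on a Bioanalyzer. How many mice stood behind a sample, and the scanner software, are not given in the sources used here.

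The deposited non-normalized table held a mean bead intensity for each of 26512 probes on each array, on the linear scale and rounded to whole numbers. Its lowest values lay well above 0, from which it was inferred that the background of the negative controls had not been subtracted. Whether the scanner software had corrected the bead values is not known. Beside each intensity stood a detection p-value, per the file headers, which falls as the intensity grows in steps set by the number of negative control beads. A deposited normalized table held intensity values on the linear scale. Their sorted values were identical in all 4 columns, from which quantile normalization by the authors was inferred. Of these values, 99.9% were whole multiples of 1/16, and their maximum of 37121 exceeded the highest non-normalized intensity of 35856, from which it was inferred that more than these 4 arrays had entered that normalization. The deposited value table of the series held 25697 probes whose intensity values were identical to those of the normalized table. It left out 815 probes, 767 of them not detected on any array. The detection p-values were the same in both tables.

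Median intensity was 93 on the 0 Gy array, 109 at 0.85 Gy, 105 at 8.5 Gy and 96 at 17 Gy. The background mean inferred from the detection p-values was 86.0, 101, 97.2 and 88.5 in that order. The number of arrays limits the precision of every value.

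The main values were made from the non-normalized intensities of all 26512 probes with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, corrects for it by normexp, adds an offset of 16, quantile-normalizes the 4 arrays and takes log2. The 25697 probes of the value table were then used, and these were named from the platform's annotation: 23978 had 1 gene symbol, 0 had several and 1719 had none, and 16593 genes were named. The Entrez identifiers of 23962 probes were found in the mouse gene table (GRCm38.p6, used for names only), and 0 symbols were updated through it. Each of the 4777 genes with several probes was represented by the probe with the highest mean raw intensity over the 4 arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the comparisons and figures.

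A gene entered a comparison if its detection p was under 0.01 on at least 1 of the arrays compared. With 1 array at each dose no difference was tested, and a fit of expression against absorbed dose over the 4 arrays was not run. The log2 difference of the dosed array minus the 0 Gy array was taken, genes at least 2-fold apart were counted, and the same was done between the dosed arrays. Where a gene was detected on only 1 of the 2 arrays, the fold is a bound, written "at least": the normalized value of the bright array was set against the higher of the dim array's own value and the lowest normalized value among its detected probes. Such a gene is described as not well above background on the dim array. Genes in which 1 array stood at least 2-fold above or below each of the others, genes shared by the comparisons with 0 Gy, and genes ordered by dose were also counted. Because these comparisons share the 0 Gy array, overlaps were set beside those of independent lists and beside 100 simulations of unchanged arrays with noise taken from the 17 and 0 Gy arrays.

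The genes named are, for each comparison with 0 Gy, the 12 with the largest differences in each direction that were at least 2-fold apart and differed the same way in the authors' normalized values, passing over gene models without a descriptive symbol. To these were added up to 4 members of each gene list that stood apart or had at least 2 members 2-fold apart in 1 direction, up to 6 genes in each direction for each array that stood apart and for the dose order, and a fixed set of genes that included Cdkn1a, Mdm2, Ccng1, Tg, Slc5a5, Tshr, Pax8, Nkx2-1, Dbp, Per2 and Arntl. There were 33 gene lists, 18 of processes and 15 of cell types that a dissected thyroid could hold. Of their entries, 638 matched a probe by symbol, 18 by synonym and 92 had no probe, among them Bax, Calca and Mki67. For each list with at least 3 measured members, the median log2 difference was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins. A list was called apart at or above percentile 97.5 or at or below percentile 2.5, as a description of these arrays. Medians were also computed with every bounded gene set at its bound.

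The comparisons, thresholds, named-gene rule, gene lists and the first set of alternatives were chosen before the data were examined. Those alternatives were the authors' normalized values, no background correction, an offset of 50, scaling to the 75th percentile, no detection filter, detection on all 4 arrays, a detection p under 0.05, the mean of all probes of a gene, 1.5-fold and 3-fold thresholds, and random lists not matched on expression. Chosen after seeing the data were counts without the members of the skeletal muscle, salivary gland and kallikrein lists, and normalization without the 0.85, 8.5 or 17 Gy array. The procedure was tested on simulated arrays made like the 8.5 and 0 Gy arrays, where 12438 probes passed the detection filter. The changed probes were drawn only from those detected on all 4 arrays. Of simulated differences of 3-fold, 90.9% of 55 were recovered, of 4-fold 95.3% of 43, of 8-fold 96.7% of 61 and of 1.5-fold, which lies under the threshold, 0% of 41. Of 12238 unchanged probes, 12 were called. The simulated noise SD was 0.12 log2 on each array. Pairs of probes gave 0.32 log2 as the SD of a single probe's difference between the 8.5 and 0 Gy arrays. That is more than the simulated SD on both arrays would give, so this share of false calls does not carry over to the data. The recovered shares do not carry over either, for the same reason and because genes detected on only 1 array were not simulated as changed.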

Results

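Transcript levels were measured in 4 samples labelled thyroid from Balb/c mice in a radioiodine series, at absorbed doses of 0, 0.85, 8.5 and 17 Gy. The labels give a time of 24 h for each sample. Each dose was represented by 1 array, so there were no replicates and no difference below has a replicate check or a p-value. The question set by the labels is how expression depends on the absorbed dose. Of the probes analysed, 9977 were detected on the 0 Gy array, 9986 at 0.85 Gy, 10455 at 8.5 Gy and 10500 at 17 Gy. Pearson's r between arrays was taken across the 8383 genes detected on at least 1 array, which are not independent replicates. It was 0.984 for 0 and 17 Gy, 0.974 for 0 and 0.85 Gy and 0.971 for 0.85 and 17 Gy. With the 8.5 Gy array it was 0.957 for 0.85 Gy, 0.953 for 0 Gy and 0.951 for 17 Gy.

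Most genes that define thyroid follicular cells were not detected on any of the 4 arrays, the 0 Gy array included. Of 23 genes of the thyrocyte list with a probe, 16 were undetected throughout. Among them was Tg, the precursor of thyroid hormone, with intensities of 84, 87, 92 and 86 in order of dose. Slc5a5, the iodide transporter, had intensities of 87, 89, 92 and 82, and the transcription factors Pax8, Nkx2-1 and Foxe1 were also undetected. The thyrotropin receptor gene Tshr was detected on each array at intensities of 137, 137, 142 and 122, as were Hhex, Slc16a10, Ano1 and the cathepsin genes Ctsb, Ctsl and Ctsk. Genes of fat were detected: 11 of 13 fat list genes were detected on all 4 arrays. The brown fat uncoupling protein gene Ucp1 had intensities of 8411, 10978, 16709 and 9249, Cidea 14223, 18726, 16544 and 11842, and the adipokine gene Adipoq 9339, 12086, 10840 and 9512. None of the 2 parathyroid and 13 cartilage genes with a probe was detected.

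**Figure D1:**
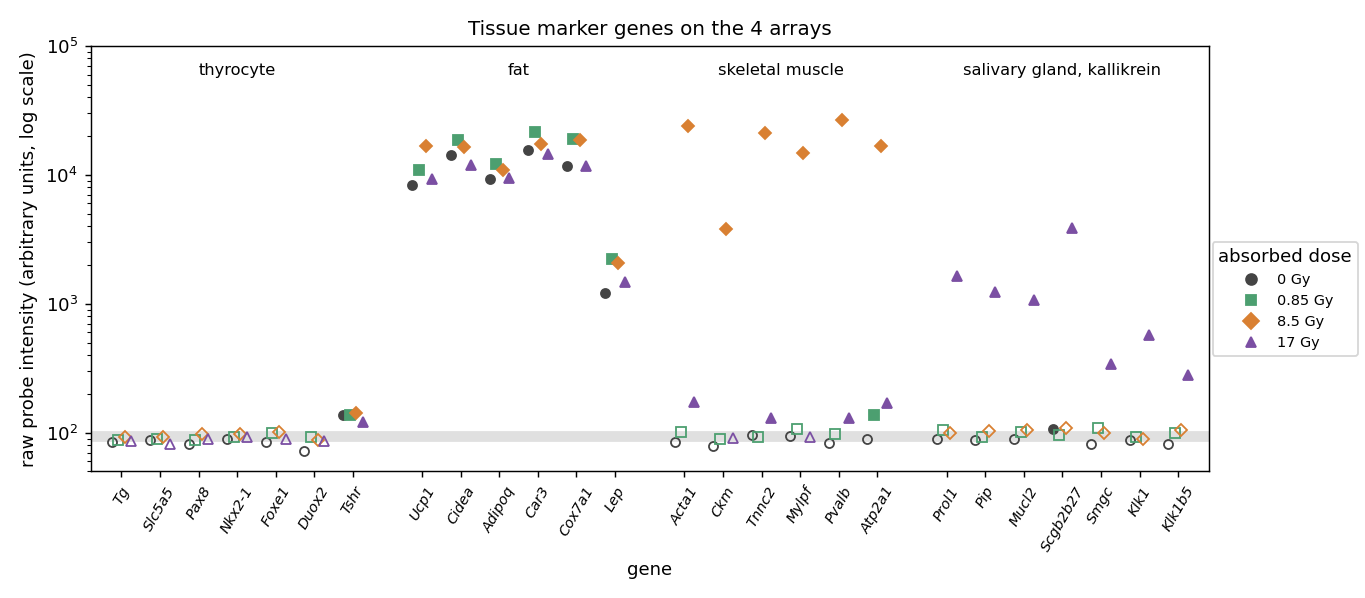
Raw intensity (log scale, arbitrary units) of thyrocyte, fat, skeletal muscle and salivary or kallikrein genes on the arrays at 0, 0.85, 8.5 and 17 Gy, 1 array per dose. Filled points were detected (detection p under 0.01) and open points were not. The grey band spans the background means of the 4 arrays, 86.0 to 101. Tg and Slc5a5 lie near that band on every array, Ucp1 lies between 8411 and 16709, and Acta1 reaches 23880 at 8.5 Gy.

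At 0.85 Gy against 0 Gy, the medians of the extracellular matrix and heat shock lists were lower, and those of the respiratory chain and MHC class I lists were higher by small amounts. Mfsd2a, a lysophospholipid transporter, was at least 30.4-fold lower and not well above background on the 0.85 Gy array. Irs2, an adaptor of insulin signalling, was 14.8-fold lower, Noct, a clock-controlled gene, 12.3-fold lower (-2.81 log2 at its other probe), and Ppargc1a, the coactivator of mitochondrial and thermogenic genes, 8.28-fold lower. Gpnmb, a glycoprotein of lipid-loaded macrophages, was 11.6-fold higher, with 0.75 log2 at its other probe, and the immediate early gene Fos was 6.53-fold higher.

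Of 7682 genes compared at 0.85 Gy, 137 were at least 2-fold higher and 283 at least 2-fold lower, and 54 and 84 of these were detected on only 1 of the arrays. In the authors' normalized values the same split was 27 higher and 94 lower. Other genes with the largest positive log2 differences were Gdpd3 at 3.98 (at least 12.9-fold), Cfap20dc at 2.76 (at least 3.6-fold), Ccn5 at 2.36 (at least 3.24-fold) and Mycl at 2.01. The chemokine gene Ccl12 was at 2.09 (at least 3.03-fold, 0.40 at its other probe), Rgs16 at 2.02 (at least 2.73-fold), Ltf at 1.95 (at least 2.15-fold), the neutrophil gene S100a9 at 1.88, the clock repressor Bhlhe40 at 1.81 and Egr1 at 1.78. On the lower side stood Ddx6 at -3.43 (-1.40 at its other probe), Megf9 at -2.79, Spon2 at -2.71 and the cyclin gene Ccnd2 at -2.64. Bach1, a repressor of antioxidant genes, was at -2.57 (at least 5.02-fold), Zbtb7a and Klf2 at -2.54 and the growth factor gene Fgf10 at -2.49 (-1.02 and -2.01 at its other probes).

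The extracellular matrix list had a median log2 difference of -0.84 over 23 measured genes at 0.85 Gy, percentile 0 among the random lists. Of its members, 7 were 2-fold lower and 0 higher. Lum, a matrix proteoglycan, was at -2.39, the collagen genes Col3a1 at -2.15 (-0.95 at its other probe) and Col5a1 at -1.41, and Mmp3 at -1.21 (-0.01 and -1.08 at its other probes). Immediate early genes went both ways, with 3 of 18 higher and 6 lower and a median of -0.70 (-0.51 with bounds). Klf2 at -2.54, Klf6 at -2.38 and Nr4a2 at -1.83 (at least 3.1-fold) were lower and Fos at 2.71 was higher. The heat shock list had a median of -0.46 over 15 genes at percentile 0.08, with Hspa1a at -1.89 (at least 2.62-fold) and Chordc1 at -1.05. Mast cell genes had a median of -0.65 over 4 genes (-0.49 with bounds, percentile 1.64).

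Respiratory chain genes had a median of 0.22 over 34 genes at 0.85 Gy, percentile 100, with 0 members 2-fold apart and the largest values in Cycs (0.97, other probe 0.01), Atp5o (0.94), Atp5pb (0.88) and Sdhd (0.71). The MHC class I list had a median of 0.27 over 15 genes (percentile 99.2), with the peptide-loading gene Tapbp at 1.23 (2.01 at its other probe) and H2-D1 at 1.06. The antioxidant list lay at 0.20 (0.15 with bounds, percentile 98.6, 23 genes), with Prdx3 at 0.83, and the proliferation list at 0.48 (0.09 with bounds, percentile 98.4, 7 genes), with Hmgb2 at 1.11. The p53 target list had a median of -0.01 over 24 genes. The apoptosis gene Bbc3 at 1.11 and Gadd45a at 1.03 (0.42 at its other probe) were higher, and Ddit4 at -1.43, Plk3 at -1.37 and the cell cycle inhibitor gene Cdkn1a at -1.02 were lower. Cdkn1a's other probes gave -0.67 and -1.05, Mdm2 was at -0.34, and Ccng1 was at -0.61 with 0.17 and 0.02 at its other probes. Markers of macrophages and neutrophils had a median of 0.26 (percentile 96.5), with S100a9, S100a8 at 1.74 and Lyz2 at 1.17 (0.16 at its other probe). Tshr was at -0.60. The clock list was at 0.14 over 16 genes, with Nfil3 at -1.76, Ciart at 1.46, Per1 at -0.91, Dbp at 0.90, Per2 at -0.06 and Arntl at -0.31. The proliferation call was lost in 6 alternative settings (median 0.06 without a detection filter), and the antioxidant call with scaling to the 75th percentile, where the respiratory chain median was 0.43, and with unmatched random lists. The immediate early and mast cell calls were lost without a detection filter (-0.13 and -0.05), the mast cell call also without background correction (-0.23), and the heat shock call with the mean of all probes (-0.20).

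At 8.5 Gy against 0 Gy, 26 of 29 measured skeletal muscle genes and some immediate early genes, Fos among them, were higher. The medians of the interferon, MHC class I and extracellular matrix lists were lower. Of the 29 muscle list genes measured, 23 were not well above background on the 0 Gy array, and among these Pvalb, a calcium buffer of fast fibres, was at least 699-fold higher, skeletal actin Acta1 at least 598-fold, troponin C Tnnc2 at least 536-fold, and the calcium pump Atp2a1 at least 423-fold. Cyp2f2 was at least 11.6-fold lower, Mfsd2a 8.73-fold, and Mup2 and Cyp2e1 6.48-fold and 6.29-fold. Fos was 10.9-fold higher.

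Of 7862 genes compared at 8.5 Gy, 207 were 2-fold higher and 285 lower, with 124 and 76 detected on only 1 array, and the authors' values gave 102 higher and 91 lower. With detection on all 4 arrays 75 were higher and 206 lower. At a 3-fold threshold 99 were higher and 46 lower, so the balance of directions depended on the setting. The muscle list had a median log2 difference of 6.30 (5.96 with bounds) over 29 genes, percentile 100, with 26 genes 2-fold higher. The myosin light chain gene Mylpf was at least 371-fold higher, Tnni2 at least 312-fold, Cox6a2 at least 121-fold and Tnnt3 at least 110-fold. Pgam2 was at least 86.0-fold higher, Mybpc2 at least 69.3-fold, and the creatine kinase gene Ckm had a bound of 6.61 on the log2 scale. Tpm2 was at 7.52, with 0.94 and 1.17 at its other probes. Mup2 at -2.69 and Mup6 at -2.50 belong to a family of near-identical genes, so which member gave the signal is uncertain. Slc7a10, an amino acid transporter of fat cells, was at -2.69, Fgf10 at -2.66 (-1.06 and -2.09 at its other probes), Nnmt at -2.64 (-2.12 at its other probe) and Pon1 at -2.53. Mmp3 was at -2.53 (-0.68 and -1.52 at its other probes), Spon2 at -2.52 and Glb1l2 at -2.35.

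The interferon list had a median of -0.82 (-0.65 with bounds) over 18 genes at 8.5 Gy, percentile 0, with 7 members lower, on the array where the muscle list stood at 6.30. Ifit3 was at -2.23 (-0.36 and -0.32 at its other probes), Oasl2 at -2.07 (-0.21 at its other probe), Irf7, a regulator of interferon genes, at -1.58 (at least 2.17-fold) and Bst2 at -1.52. MHC class I genes had a median of -0.60 (-0.56 with bounds, percentile 0.02) over 15 genes, with H2-D1 at -1.18, Nlrc5, a transactivator of class I genes, at -1.12, H2-T23 at -1.11 (-0.82 at its other probe) and H2-Q7 at -1.08. All 23 extracellular matrix genes were lower than on the 0 Gy array (median -0.84, percentile 0), 9 of them 2-fold. Lum was at -2.19, Thbs2 at -1.60 and Col3a1 at -1.56 (-1.05 at its other probe). The smooth muscle list had a median of -0.82 over 8 genes (percentile 0), of which 5 were negative and 3 positive, 2 were 2-fold lower and 1 2-fold higher, with Myh11 at -1.55 and Acta2 at -1.19 lower and Des, which skeletal muscle also expresses, at 1.84. The endothelial list was at -0.35 (15 genes, percentile 0.65), with Pecam1 at -1.04 (-0.54 at its other probe) and Vwf at -0.85. The mast cell list was at -0.95 (-0.81 with bounds, percentile 0.29), with Cpa3 at -1.23 (-0.79 at its other probe). The heat shock list was at -0.37 (14 genes, percentile 0.65), with Hspa1a at -1.91 (at least 2.85-fold) and Cryab, abundant in muscle, at 2.88.

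On the same array, the 7 measured thyrocyte list genes had a median of -0.60 (percentile 0.95), with Ctsk at -1.15, Hhex at -0.76, Slc16a10 at -0.74, Ctsl at -0.60 and Tshr at -0.32. Tg, Slc5a5, Pax8, Nkx2-1 and Foxe1 were undetected and are not among the measured genes, so this median says nothing about them. Erythrocyte genes were at 0.75 (0.71 with bounds, 5 genes, percentile 99.9), with Hbb-b2 at 1.14, Slc4a1 at 0.95 (at least 1.64-fold) and Hba-a1 at 0.75. The globin genes have near-identical copies. Respiratory chain genes were at 0.14 (percentile 99.96), with Cycs at 1.14 (0.22 at its other probe) and Atp5pb at 1.01. The clock list was at 0.20 (percentile 98.6), with Bhlhe40 at 1.67, Dbp at 0.94, Per1 at -1.61, Arntl at -0.62 and Per2 at 0.12. Among immediate early genes (median 0.08, -0.01 with bounds, 5 higher and 1 lower), Egr1 was at 1.99, Junb at 1.65 and Klf2 at -1.34. In the p53 target list (median 0.09, 0.08 with bounds), Cdkn1a was at -1.28 (-0.70 and -1.30 at its other probes), Mdm2 at -0.24 and Ccng1 at 0.52. Ddit4, an inhibitor of mTOR signalling, was at -2.13 and Ak1, abundant in muscle, at 1.27. The thyrocyte call was lost with the authors' values (-0.28), without background correction (-0.22) and without a detection filter (-0.08), the clock call in 3 settings, the heat shock call in 4 (nearest 0 at -0.18), the endothelial call with the mean of all probes (-0.19) and the smooth muscle call without a detection filter (-0.28). Calls that held at medians over 1.5 times smaller included those of muscle (2.48 with detection on all 4 arrays), interferon, MHC class I and erythrocyte genes (-0.40, -0.27 and 0.42 without background correction) and mast cells (-0.32 without a detection filter), while the respiratory chain median was 0.33 with scaling to the 75th percentile.

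At 17 Gy against 0 Gy, 5 of 6 measured salivary gland genes and 3 of 6 kallikrein genes were at least 2-fold higher. The medians of the macrophage, MHC class II and chemokine lists were higher and that of the endothelial list was lower. Scgb1b27 was at least 112-fold higher, Scgb2b26 at least 92.7-fold and Scgb2b27 111-fold. The proline-rich protein gene Prol1 was at least 48.1-fold higher and Pip, a secreted protein of salivary and lacrimal glands, at least 35.6-fold. The monocyte chemoattractant genes Ccl7 and Ccl8 had log2 differences of 1.75 (at least 2.04-fold) and 1.40, and Ccl5 1.27. Cdh5, the cadherin of endothelial junctions, was at -1.23.

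Of 7839 genes compared at 17 Gy, 69 were 2-fold higher and 36 lower, with 42 and 22 detected on only 1 array, and the authors' values gave 17 higher and 2 lower. The salivary list had a median of 5.70 (5.04 with bounds) over 6 genes, percentile 100, with 5 genes higher. Without a detection filter, over all list genes with a probe, its median was 0.13 (percentile 99.5). The kallikrein list had 1.82 (1.38 with bounds) over 6 genes, percentile 100, with 3 higher. Without a detection filter its median was 0.01 (percentile 62.9) and at detection p under 0.05 it was 0.30 (percentile 92.1), so the kallikrein call rested on the few genes detected. Of the kallikrein genes, Klk1 was at least 15.1-fold higher, Klk1b5 at least 6.25-fold and Klk1b27 at least 4.94-fold. Mucl2 was at least 30.4-fold higher, Mup5 at least 10.3-fold and Smgc at least 8.02-fold (2.84 and 1.54 log2 at the other probes of Mup5 and Smgc). The Scgb, Mup and Klk1b genes have near-identical relatives, so which member gave the signal is uncertain. The muscle list was at 0.35 (0.23 with bounds, 13 genes, percentile 99.99), with 6 genes higher, among them Acta1 (at least 2.94-fold), Atp2a1 (at least 2.91-fold), Pvalb (at least 1.67-fold) and Tnni2 (at least 1.35-fold).

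All 13 measured genes of macrophages and neutrophils were higher at 17 Gy (median 0.84, percentile 100), 3 of them 2-fold, on the array where the salivary list stood at 5.70. The largest differences were in S100a8 (1.23), Lyz2 (1.07, with 0.07 at its other probe), the complement gene C1qa (1.01) and Cd52 (0.94). The MHC class II list had a median of 0.85 over 7 genes (percentile 100), with H2-Eb1 at 1.02, H2-DMa at 0.93, H2-DMb1 at 0.88 and H2-Ab1 at 0.85. Chemokine and cytokine genes were at 0.93 (0.55 with bounds, 15 genes, percentile 100; 0.13 without a detection filter), with 4 higher, Ccl4 at 1.17 (at least 1.47-fold) among them. MHC class I genes were at 0.25 (percentile 99.95), with Tapbp at 1.11 and Psmb8 at 0.74. Immediate early genes were at 0.22 (percentile 99.9), with Ccn1 at 0.80, Fos at 0.59 and Egr1 at 0.55. DNA repair genes were at 0.17 (0.10 with bounds, percentile 98.2, 20 genes), with Pcna at 0.60 and Msh6 at 0.52.

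Endothelial genes had a median of -0.32 over 15 genes at 17 Gy, percentile 0, with Sox17 at -0.56 and Plvap at -0.50 beside Cdh5. Extracellular matrix genes had -0.17 over 26 genes, percentile 0.42, with Mmp3 at -0.77, Col3a1 at -0.75 and Timp1 at 0.80 (at least 1.38-fold). Genes lower and not well above background at 17 Gy were Acvr1c (at least 3.1-fold), Gldn (at least 1.92-fold), Atp5k (at least 1.66-fold), Slc5a3 (at least 1.69-fold), Tmem119 (at least 1.72-fold), Wrap73 (at least 1.55-fold, -0.39 log2 at its other probe) and the clock activator Arntl (at least 1.62-fold). Alcam was at -1.31, Aoc3, an amine oxidase of adipocytes and vessels, at -1.23, Ncan at -1.22 and Cd209d at -1.21. Cdkn1a was at -0.37 (0.05 and -0.48 at its other probes), Mdm2 at -0.14, Ccng1 at -0.10 (0.51 and 0.00 at its other probes), Tshr at -0.53 (-0.07 at its other probe), Dbp at 0.74 and Per2 at 0.47. The p53 target list was at -0.07. The muscle call was lost when detection on all 4 arrays was required (0.13), the extracellular matrix call without a detection filter (-0.09) and the DNA repair call in 5 settings (0.08 without background correction). Besides the salivary and chemokine lists, calls that held at medians over 1.5 times smaller included those of MHC class II (0.32 without a detection filter), and of macrophage and immediate early genes (0.55 and 0.13 without background correction).

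**Figure D2:**
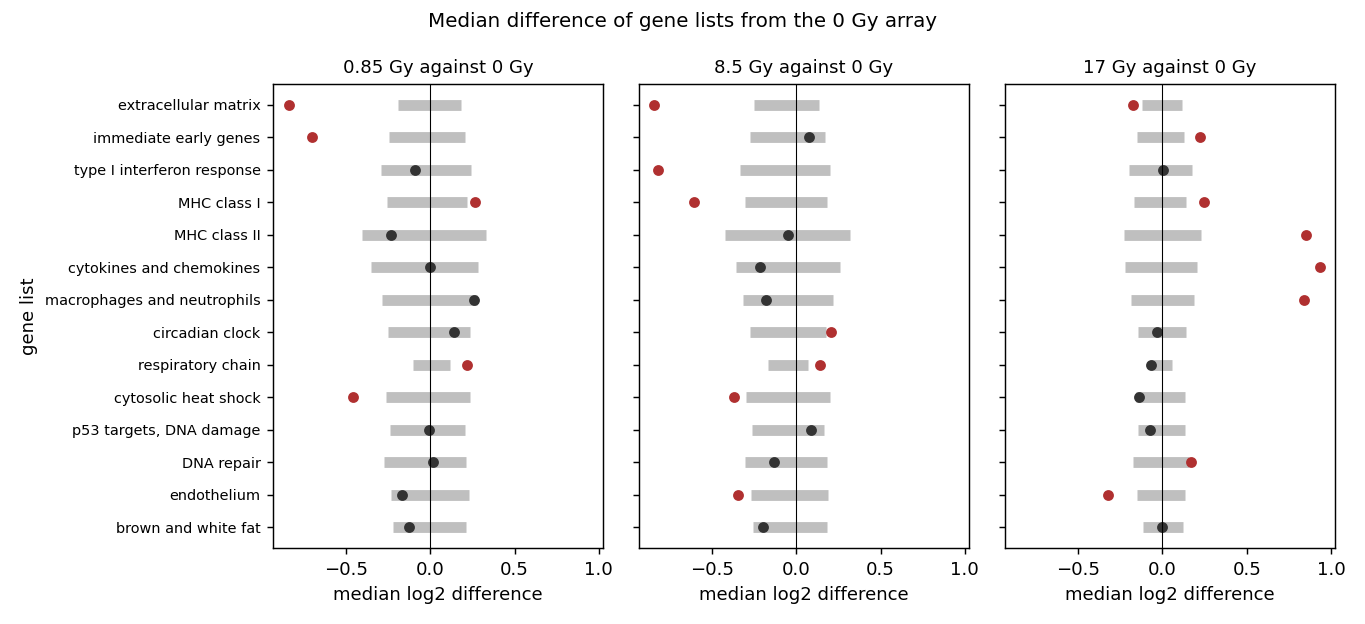
Median log2 difference from the 0 Gy array (horizontal axis) of 14 gene lists at 0.85, 8.5 and 17 Gy, 1 array per dose. Dots are the list medians, red where they lie outside the grey bars, which span the range of 10000 matched random lists within which a list was not called apart. The muscle list, at 6.30 at 8.5 Gy, and the salivary list, at 5.70 at 17 Gy, are not drawn.

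Between the dosed arrays, muscle genes separated 8.5 Gy from the other doses and salivary genes separated 17 Gy. From 0.85 to 8.5 Gy, 256 of 7822 genes were 2-fold higher and 116 lower (131 and 27 in the authors' values), with the muscle list at 6.09 (5.96 with bounds), and the immediate early list at 0.72 (0.49 with bounds). The interferon list was at -0.82 (-0.73 with bounds) and MHC class I at -0.61. From 8.5 to 17 Gy, 279 of 8038 genes were higher and 213 lower (89 and 100 in the authors' values). With detection on all 4 arrays 192 were higher and 81 lower, and at a 3-fold threshold 60 and 101. The muscle list was at -6.18 (-6.08 with bounds) and the salivary list at 5.48 (5.05 with bounds). The interferon list was at 0.88 (0.58 with bounds), MHC class I at 0.83, MHC class II at 0.93 and extracellular matrix at 0.69 (0.60 with bounds). From 0.85 to 17 Gy, 271 of 7852 were higher and 106 lower (93 and 18 in the authors' values), with the salivary list at 5.84 (5.04 with bounds). Extracellular matrix was at 0.64 (0.60 with bounds), MHC class II at 0.79 (0.72 with bounds) and chemokines and cytokines at 0.59. Percentiles of these medians among random lists were 99.9 or higher where positive and 0 where negative.

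**Figure D3:**
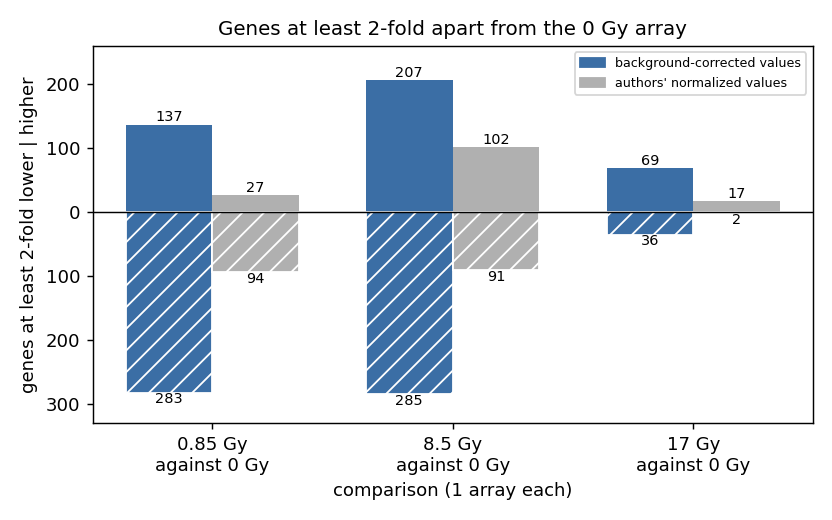
Number of genes (vertical axis) at least 2-fold higher (plain bars) or lower (hatched bars) in each comparison, 1 array per dose, in background-corrected values (blue) and in the authors' normalized values (grey). At 17 Gy against 0 Gy the counts are 69 higher and 36 lower against 17 and 2 in the authors' values, and at 8.5 Gy against 0 Gy 207 and 285 against 102 and 91.

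The 8.5 Gy array stood 2-fold or more above each of the other arrays in 118 genes, 26 of them from the muscle list and led by Mylpf, Pvalb, Tnnc2, Tnni2, Acta1 and Cox6a2. It stood below in 39 genes, led by Cyp2f2, Mup2, Mup6, Cyp2e1, Bst2 and Pon1. Among genes detected on all 4 arrays, the 8.5 Gy array stood above in 26 and below in 31. The 0.85 Gy array stood above in 11 genes, led by Gdpd3, Gpnmb, Cfap20dc, the macrophage elastase gene Mmp12, Ccn5 and Cdc123. It stood below in 56, led by Irs2, Mfsd2a, Ddx6, Bach1, Klf6 and Ppargc1a. The 17 Gy array stood above in 19 genes, 8 of them from the salivary and kallikrein lists, led by Scgb1b27, Scgb2b26, Scgb2b27, Prol1, Pip and Mucl2, and below in 2, Ncan and Atp5k. The 0 Gy array stood above in 14 genes, among them Alcam, Slc5a3, Aoc3, Cd209d, Tmem119 and Plau, and below in 3, Acat1, S100a8 and Atp2a1.

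Those 3 genes were 2-fold higher in all 3 comparisons with 0 Gy. The 14 lower in all 3 were Alcam, Aoc3, Cd209d, Cep85, Elovl4, Glb1l2, Gpat3, Plau, Psat1, Sema5a, Slc5a3, Sncg, Spon1 and Tmem119. Unchanged arrays simulated against a shared control gave 1.51 higher and 1.23 lower. In the authors' values, and without background correction, 0 genes were higher and 2 lower in all 3 comparisons. At a 3-fold threshold there were 0 in either direction. At 0.85 and 8.5 Gy, 32 genes were higher and 116 lower in both comparisons, where independent lists would share 3.38 and 9.62 and simulated unchanged arrays 4.7 and 4.59. At 0.85 and 17 Gy the numbers were 15 and 19 (independent 1.13 and 1.22, simulated 5.09 and 4.64), and at 8.5 and 17 Gy 12 and 18 (independent 1.70 and 1.22, simulated 4.6 and 4.52). The covariance of the log2 differences was 0.151 for 0.85 and 8.5 Gy against 0.0522 simulated, 0.0675 against 0.0522 for 0.85 and 17 Gy, and 0.0695 against 0.0523 for 8.5 and 17 Gy. Pearson's r across genes lay below the simulated value in each pair, at 0.44, 0.34 and 0.26 in the same order against 0.50 simulated for each. The simulated noise came from the 17 and 0 Gy arrays, whose log2 differences had the smallest SD of the comparisons with 0 Gy (0.40, against 0.53 at 0.85 Gy and 0.70 at 8.5 Gy). It was drawn as normal noise from a robust SD in bins of mean expression, which gives little weight to large differences. Over all genes compared, the robust SD was 0.29 at 17 against 0 Gy. Whether the excess over the simulated values would remain with the plain SD was not tested. The 1 array at 0 Gy could not be split, and part of the excess over independent lists may come from it. The genes shared by all 3 comparisons are by definition those in which the 0 Gy array stood apart. For them, an effect of dose cannot be told apart from a trait of that 1 array.

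Genes ordered by dose were few: 9 were higher with each dose and at least 2-fold higher at 17 than at 0 Gy, and 13 were lower with each dose. In the authors' values, and without background correction, there was 1 such gene, higher with dose, and among genes detected on all 4 arrays there were 4 higher and 2 lower. Among all 24 orders of the arrays, with a median of 36 genes and a range from 3 to 127, these 2 orders ranked 23 and 22. Each order needs a 2-fold gap between its end arrays. The 17 and 0 Gy arrays had the fewest genes that far apart, 69 higher and 36 lower. The low ranks of these 2 orders therefore cannot show a lack of dose order. With the same end arrays, the order 0, 8.5, 0.85, 17 Gy held 17 genes against 9, and 17, 0.85, 8.5, 0 Gy held 3 against 13. The highest count, 127, belonged to the order 0.85, 8.5, 17, 0 Gy from lowest to highest. Of the genes detected on all 4 arrays, the lectin gene Clec4a3 at 1.40 and Ccl5 at 1.27 were higher with dose, and Cdh5 at -1.23 and Rusc2 at -1.15 (-0.68 at its other probe) lower. Zbtb41 (at least 2.04-fold higher at 17 Gy) was not detected at 0 Gy, and Atp5k, Arntl and Wrap73 were not detected at 17 Gy. Klk1b5 was detected at 17 Gy only, Sel1l3 and Zfp930 at 8.5 and 17 Gy only and Syce1l at 0 Gy only, so their place in the order rests in part on values at background.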

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

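The named-gene comparisons left out the probes without a gene name and the probes missing from the series' value table, and differences seen in these unused data drew attention to them. These counts were not among the planned comparisons and were made after the data were seen. Of 1719 probes without a gene name, 609, 625 and 615 passed the detection filter at 0.85, 8.5 and 17 Gy against 0 Gy. Of these, 44 were at least 2-fold apart at 0.85 Gy against 0 Gy, 16 higher and 28 lower. At 8.5 Gy 38 were apart, 14 higher and 24 lower, with a largest log2 difference of 6.44. At 17 Gy 14 were apart, 9 higher and 5 lower, with a largest log2 difference of 2.87. Of the 815 probes missing from the value table, 28, 30 and 31 passed the filter, and 1 was 2-fold apart at 17 Gy, lower at -1.05 log2, and 0 at the other doses.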

How the results depend on the processing

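Counts without the muscle, salivary and kallikrein lists and normalization without the 0.85, 8.5 or 17 Gy array were chosen after seeing the data, and the other settings were planned. The counts of genes at least 2-fold apart depended on how the background was treated. The counts below follow 1 order: 0.85, 8.5 and 17 Gy against 0 Gy, then 8.5 against 0.85 Gy, 17 against 8.5 Gy and 17 against 0.85 Gy. The main counts were 420, 492, 105, 372, 492 and 377. Genes in which the 0, 0.85, 8.5 or 17 Gy array stood apart numbered 17, 67, 157 and 21, genes shared by the comparisons with 0 Gy 17, and dose-ordered genes 22. Where a count was computed for a setting and is not given, it lay within 1.5 times the main count. Normalization without the 0.85, 8.5 or 17 Gy array gave counts only for the comparisons among the arrays left.

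With the authors' normalized values the counts were 121, 193, 19, 158, 189 and 111, those of arrays apart 2, 22, 89 and 13, shared genes 2 and dose-ordered genes 1. Without background correction they were 108, 177, 16, 133, 172 and 100, arrays apart 2, 18, 81 and 13, shared 2 and dose-ordered 1. With an offset of 50 they were 179, 240, 23, 180, 247 and 157, with 3, 32 and 13 genes for the 0, 0.85 and 17 Gy arrays, 3 shared and 2 dose-ordered. These settings leave or add a constant under each intensity, which by construction shrinks the ratios of dim genes. When detection on all 4 arrays was required, which leaves fewer genes, the counts were 278, 281, 38, 170, 273 and 247, arrays apart 9, 38, 57 and 7, shared 9 and dose-ordered 6. At a 1.5-fold threshold they were 1695, 1744, 761, 1353, 1700 and 1590, arrays apart 165, 311, 410 and 161, shared 165 and dose-ordered 125. At a 3-fold threshold they were 83, 145, 18, 137, 161 and 75, arrays apart 0, 19, 89 and 12, shared 0 and dose-ordered 1. Changing the threshold changes these counts by construction. With scaling to the 75th percentile, dose-ordered genes numbered 14, and the cause was not tested. Without the members of the muscle, salivary and kallikrein lists, the 17 Gy array stood apart in 13 genes, since 8 of its genes belong to those lists.

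No detection filter and a detection p under 0.05 gave exactly the main counts. No gene undetected on the arrays compared reached 2-fold, so these settings say little about how firm the counts are. The mean of all probes and normalization without the 0.85, 8.5 or 17 Gy array left each count they gave within 1.5 times the main one. The value table of the series was identical to the authors' normalized table and gave no values of its own. For named genes, 1827 values over 261 results were recomputed: 1608 kept direction and side of the threshold, 213 kept direction under 2-fold, 6 newly passed it and 0 reversed. For gene lists, 836 of 889 values kept their side, 33 lost and 20 gained a call, and 0 reversed. Of 31 list calls against 0 Gy, 17 held in every setting run for them. The calls gained were those of the respiratory chain at 17 Gy, lower in 7 settings (the authors' values among them), heat shock at 17 Gy, lower in 4, erythrocytes at 0.85 Gy, higher in 5, macrophages and neutrophils at 0.85 Gy, higher in 2, and chemokines at 0.85 and 8.5 Gy, lower when detection on all 4 arrays was required (-0.51 and -0.45). The largest shift of the median of all genes from its main value was 0.0672 log2, with scaling to the 75th percentile. No paired analysis was possible because each dose has 1 array. Signal over background limits the dim genes: of the genes 2-fold higher or lower, 54 and 84 at 0.85 Gy, 124 and 76 at 8.5 Gy and 42 and 22 at 17 Gy were detected on only 1 array. Between probes of the same gene, r of the log2 differences was 0.54, 0.56 and 0.28 in order of dose, across 1533, 1571 and 1592 pairs, and the second probe went the same way in 65 of 72, 54 of 61 and 8 of 8 genes called, but was itself 2-fold apart in only 28, 26 and 1 of them.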

Other observations

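The tests of explanations in the last 3 paragraphs were all chosen after the results were seen, whereas the gene lists described first were fixed in advance. The lipid list was not called apart, with medians of -0.10, -0.15 and 0.01 at 0.85, 8.5 and 17 Gy over 22, 22 and 23 genes. Pdk4, which restrains glucose oxidation, was at -1.06 at 0.85 Gy, and Angptl4, an inhibitor of lipoprotein lipase, at -1.11 at 8.5 Gy. Ppargc1a was lower at both doses, at -3.05 and -1.07. The fat list had medians of -0.13, -0.20 and 0.00. Chemokine and cytokine genes went both ways at the lower doses, with medians of 0.00 (0.01 with bounds) and -0.22. Ccl9 was at -1.62 and -1.55, Ccl8 at -1.47 at 8.5 Gy, and Cxcl1 was at least 1.78-fold higher at 0.85 Gy and at least 2.43-fold at 8.5 Gy. In the unfolded protein list (medians -0.05, -0.08 and 0.05), the stress transcription factor gene Ddit3 was at 1.47 and the chaperone gene Pdia3 at -1.14 at 0.85 Gy. S100a8 and S100a9, neutrophil genes, were at 1.46 and 1.21 at 8.5 Gy, where the macrophage and neutrophil list was at -0.18.

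Several other lists lay inside the range of the random lists in the main values. Ribosomal protein genes had medians of 0.08, -0.07 and -0.03, and the nerve list 0.13, 0.09 and -0.31 (0.11, 0.20 and -0.18 with bounds). The airway list had -0.43 (-0.23 with bounds), -0.40 and -0.15. At 0.85 Gy, interferon genes were at -0.09, MHC class II at -0.23 (-0.05 with bounds), DNA repair at 0.02, the thyrocyte list at -0.14, muscle at -0.02, endothelium at -0.17, smooth muscle at -0.04 and erythrocytes at 0.39. At 8.5 Gy, MHC class II was at -0.05, DNA repair at -0.13 (-0.11 with bounds), proliferation at 0.19, antioxidant genes at -0.07 and the salivary list at -0.50 (-0.27 with bounds). At 17 Gy, heat shock was at -0.14 and the respiratory chain at -0.07, and these lists were called lower in 4 and 7 alternative settings. At the same dose, interferon genes were at 0.00, clock genes at -0.03, proliferation at 0.19 (0.07 with bounds), antioxidant genes at -0.01 (-0.05 with bounds), the thyrocyte list at -0.11, T cells at -0.03 (-0.15 with bounds), mast cells at 0.24, erythrocytes at 0.14 and smooth muscle at -0.14. Lists with under 3 measured genes were T cells and kallikreins at 0.85 and 8.5 Gy, salivary genes at 0.85 Gy, and B cells and C cells at every dose. Their medians were -0.84 and -0.51 for T cells, -0.23 and -0.11 for kallikreins (0.14 and 0.22 with bounds, so the direction turned) and -0.97 for salivary genes (-0.55 with bounds). The 1 B cell gene measured at 0.85 Gy was at 0.79 (0.04 at its bound) and the 1 C cell gene measured at 17 Gy at 0.87 (0.58 at its bound). No parathyroid or cartilage gene was measured.

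Xist, expressed from the inactive X chromosome, was detected on all 4 arrays with intensities of 160, 150, 161 and 158, and the Y-linked Eif2s3y and Kdm5d on none. Uty was detected on the 8.5 Gy array only, at 115, with 95, 115 and 94 at 0, 0.85 and 17 Gy.

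On all 4 arrays 16 of 23 thyrocyte list genes stayed at background, while the other 7 and 11 of 13 fat genes were detected. Loss of thyroid cells after irradiation is argued against as the source of this pattern by the 0 Gy array, where the same 16 genes were undetected. That array detected as many thyrocyte list genes as the dosed array with the fewest, a difference of 0 that follows from the pattern itself. Genes undetected at 0 Gy cannot show whether thyroid cells were lost at the other doses. RNA mostly from fat is a candidate explanation, given those 11 fat genes, with Car3 at 15611 and Cidea at 14223 on the 0 Gy array. Of the 13, 1 is also in the lipid list, and how many thyroid tissue expresses was not analysed here. Probes that do not hybridise stay open, since the 22 probes of the 16 undetected genes, at intensities of 72 to 110, were detected on no array, and arrays of other tissues were not analysed here. Of the 16 genes, 6 had more than 1 probe, and for these several probes would have to fail together.

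Muscle genes stood out on the 8.5 Gy array, with 26 of 29 at least 2-fold higher, against 6 of 13 at 17 Gy. The muscle values did not grow from 8.5 to 17 Gy: 2 of 29 measured genes were at least as high at 17 Gy. A change that grows with absorbed dose would not give this order, but the count largely follows from the pattern itself. On the 8.5 Gy array 26 muscle list genes stood at least 2-fold above each other array, so this count is not a separate test. The normalization is argued against by the raw intensities, whose median ratio of 8.5 over 0 Gy was 26.3. Skeletal muscle in the 8.5 Gy sample is a candidate explanation, with Pvalb at a raw intensity of 26621 and Acta1 at 23880. The 89.7% of the measured list at least 2-fold higher restates the pattern and is not a separate test. Of the 34 list genes with a probe, 29 were measured, and 23 of these passed the detection filter only through the 8.5 Gy array. A response limited to 8.5 Gy was not tested and stays open.

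Salivary and kallikrein genes stood out on the 17 Gy array. Salivary gland in the 17 Gy sample may explain them in part: 27.5% of the 40 genes of both lists were detected there and 8 genes only there, while Dcpp1, Bpifa2, Aqp5, Car6 and Lpo were undetected and 17 of 23 kallikrein genes were detected on no array. How many of the 40 genes salivary gland expresses was not analysed here. A change that grows with absorbed dose had a list median of -0.50 at 8.5 Gy, (-0.27 with bounds) over 3 genes that went both ways, 2 of them detected on only 1 of the arrays. With 1 array at 17 Gy these explanations cannot be told apart.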
